A study of Drosophila melanogaster with 2 samples.

How the data were processed

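Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of 0 to 24 hours, both sexes pooled, from a transgenic line that stably expressed tup with a C-terminal GFP tag. Per the labels, an anti-GFP antibody was used, chromatin was sheared by sonication to fragments of 200 to 800 bp, and 2 biological replicates were made. The replicates carry separate biosample records of the same line, and both belong to 1 group. A control experiment entered the authors' peak calling. It was not analysed here.

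The deposited files were peak lists in the dm6 and dm3 genome builds. In each build there was a candidate list for each replicate and a candidate list called on both replicates pooled. An optimal list was thresholded by the authors' test of reproducibility between replicates (IDR, irreproducible discovery rate). Per the file lists deposited with each sample, the candidate lists were called against a control alignment, and the optimal list was derived from both replicate lists and the pooled list. The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here. The height of each peak is the caller's signal value, as deposited by the authors. It was used only to rank and describe peaks within a list, because its scale differs between lists. The deposited lists also hold a -log10 q value per peak, which reached a ceiling shared by 784 of the pooled dm6 peaks, so peaks were ranked by signal. The third value used was the summit position within each peak. Each candidate list held 30000 peaks except the pooled dm3 list, which held 27123. Read totals are not given in these lists, so the depth of each replicate is unknown.

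Coordinates are those of dm6, counted from 1. The annotation was Ensembl release 115 for assembly BDGP6.54, and the sequence was the RefSeq copy of the same assembly. All pooled dm6 candidates lay within its chromosome lengths (0 ended past a chromosome end). Coordinates were never converted between builds, and dm3 lists were used for counts and shares only. The 5889 annotated transposable elements were left out of the genes, which left 18277 genes on arms 2L, 2R, 3L, 3R, 4, X and Y.

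Each summit was assigned to the first class that applied among promoter (within 500 bp of an annotated transcription start site, TSS), 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. Optimal summits were compared with the 27394 pooled candidates that overlapped no optimal peak, called non-passing candidates below, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over classes or arms. A gene was called bound when an optimal summit lay between 5 kb upstream of its start and its end. The number of bound members of each of 22 gene lists was compared with 100000 random lists drawn from the same deciles of region length, in a two-sided permutation test adjusted over the lists. The smallest p it can give is 2e-05. Of the listed names, 4 did not match a single gene of the annotation and were left out. Genes of 1 list that lie side by side can share a peak, so they are not fully independent. For motif shares, 11 motifs and all sequences of 6 bp were counted on either strand within 50 bp of the summit (101 bp in all), against 2241 non-passing candidates drawn at random from the same GC deciles, with Fisher's exact test. Median signal of promoter and other optimal peaks was compared with a two-sided permutation test of 100000 resamples, whose smallest p is 1e-05. The tup region was compared with 10000 random windows of the same length.

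The replicates were compared by the share of the 2241 strongest peaks of each that had a summit within 100 bp in the other, with 1000 circular shifts along the chromosomes as chance level. Peaks are not independent replicates: p-values and Wilson 95% confidence intervals over peaks or genes describe these lists and cover counting error only. Feature, arm, list, motif and tup locus results were repeated on the 2241 strongest peaks of each replicate alone. These values are printed where a call changed or the value moved by more than 1.5 times, and for some other results. For a share of 0, the limit is the share that 3 counts would give.

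Groups, gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule names tup, the genes nearest to the 15 strongest optimal peaks, the 10 genes with most optimal summits in their region (ties broken by the highest signal), and per list up to 4 bound members with the highest signal and up to 2 unbound members first in alphabetical order. Alternatives covered the overlap criterion, the number of peaks, the build, the TSS distance, the background, the assignment of peaks to genes, the matching, the motif window, the tup window and each replicate alone. The planned matching on candidate peaks counts the optimal peaks too, so it partly conditions on being bound. Added after the data were seen were a background of protein-coding genes, transposable elements counted as genes, matching of genes on their number of non-passing candidates, motif backgrounds matched on feature class, and 100 other random draws of the GC-matched background.

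Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The list test was tested on simulated lists drawn from the 18277 genes. Of 500 random lists of genes, 1.8% had p below 0.05. Lists with 50% bound genes were recovered at p below 0.05 in 100% of 200 simulations at 40 genes. At 20 genes this was 99.5% and at 10 genes 18.5%. Members were planted at random, whatever their region length, and p was not adjusted over lists. The simulation thus does not give the power for lists with more bound genes expected. Axon guidance genes, with 50% of 30 bound, had 11.6 expected (permutation test, raw p = 0.274). The motif test recovered an Islet-type site planted in 5% of windows in 100% of 20 simulations.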

Results

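Genomic binding of tailup (tup), the fly Islet-type LIM-homeodomain transcription factor, was profiled by anti-GFP ChIP-seq in whole embryos of 0 to 24 hours that carried a GFP-tagged tup transgene. The data were 1 group of 2 biological replicates. The optimal dm6 list held 2241 peaks, with a median width of 384 bp and a caller's signal value from 68.7 to 1283, median 102. These were exactly the 2241 strongest of the 30000 pooled candidates. The list thus equals a cut on pooled signal, and a peak in it need not be found in each replicate. The dm3 list held 2129 optimal peaks. Depth is unknown because the lists carry no read totals.

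The first comparison was between replicates. Of the 2241 strongest peaks of replicate 1, 1229 (54.8%, Wilson 95% interval 52.8 to 56.9) had a summit within 100 bp of one among the 2241 strongest of replicate 2. Circular shifts gave a mean of 0.341%, with a highest value of 0.848%. Over the 2025 optimal peaks with a candidate in both replicates, log2 signal had a Pearson r of 0.55 and a Spearman rho of 0.45 across peaks, which are not independent replicates. Selection on pooled signal limits the range of signal, so these values do not measure agreement over all candidates. The shared share moved to 62.3% when any overlap of the intervals counted. Of the strongest 560 optimal peaks, 99.1% were matched among the 2241 strongest of replicate 1 and 95.5% among those of replicate 2. Of the weakest 561, 52.0% and 42.4% were.

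The strongest peaks lay near genes of varied function. The peak with the highest signal (1283) was at 2L 480916 to 481272, within an intron of ush, the FOG-family cofactor of GATA factors, and 1388 bp from the nearest TSS, that of the zinc finger gene cbt. The next were at the promoters of CG14100 (3L 19590450 to 19590796, signal 1172) and Ugalt, a UDP-galactose transporter gene (X 2703715 to 2704064, signal 1066), and in an intron of CG11050 (2L 6612526 to 6612874, signal 1019). Of the 15 strongest peaks, 10 were promoter peaks and 5 were intronic. The promoter peaks also included those of px (signal 849), Chro, which encodes the chromosomal protein Chromator (signal 844), the Polycomb-group gene ph-p (signal 794), Tcs5 (783), PNPase (781), lncRNA:CR31840 (695), CG1888 (683) and CenG1A (672). The intronic peaks included those of the kinase gene Lk6 (signal 744), the adherens junction gene cno (650) and CG32772 (649.9). All 15 had a candidate in both replicates, with replicate 1 signals from 333 to 760 and replicate 2 signals from 262 to 528.

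The genes with the most optimal summits in their regions are given by count, which was not adjusted for region length. The long non-coding RNA gene lncRNA:CR44357 had 11 optimal summits in its region of 244347 bp, and CG1677, which overlaps it on X, had 9. The genes ush, tara, sbb and kirre had 10 each, in regions from 39679 bp (tara) to 399149 bp (kirre). Raf, the MAP kinase kinase kinase of receptor tyrosine kinase signalling, CHES-1-like and msn, a JNK pathway kinase, had 7 each. The cAMP phosphodiesterase gene dnc had 6. The strongest peak of CHES-1-like had a signal of 166 in replicate 1 and 22.5 in replicate 2, on lists whose median signals were 20.8 and 11.03.

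Optimal summits were concentrated at promoters and almost absent from coding exons. Promoters held 1237 of 2241 optimal summits (55.2%, Wilson 95% interval 53.1 to 57.2) and 21.03% of the 27394 non-passing candidates (odds ratio 4.63, Fisher's exact test, adjusted p = 1.47e-247). The promoter share was 55.9% for the strongest peaks of replicate 1 and 53.6% for those of replicate 2. Coding exons held 7 optimal summits (0.312%, interval 0.151 to 0.643) against 15.2% of non-passing candidates (Fisher's exact test, adjusted p = 4.91e-139). The 3' UTR share was 0.446% against 3.52% (odds ratio 0.123, Fisher's exact test, adjusted p = 2.34e-21), with an odds ratio of 0.265 for replicate 2 alone. Introns held 31.4% against 38.9% (Fisher's exact test, adjusted p = 1.67e-12), and intergenic DNA 11.1% against 19.7% (adjusted p = 2.02e-25). The 5' UTR share (0.446% against 0.810%, Fisher's exact test, adjusted p = 0.0711) and the share in non-coding exons (1.12% against 0.942%, adjusted p = 0.428) did not differ past the threshold. The 5' UTR share passed it with a TSS distance of 1000 bp (Fisher's exact test, adjusted p = 0.0415) and for replicate 2 alone (adjusted p = 0.00618). The non-coding exon odds ratio of 1.19 turned to 0.472 above the median signal and to 0.861 for replicate 1 alone. Neither passed (Fisher's exact test, adjusted p = 0.118 and 0.586).

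**Figure D1:**
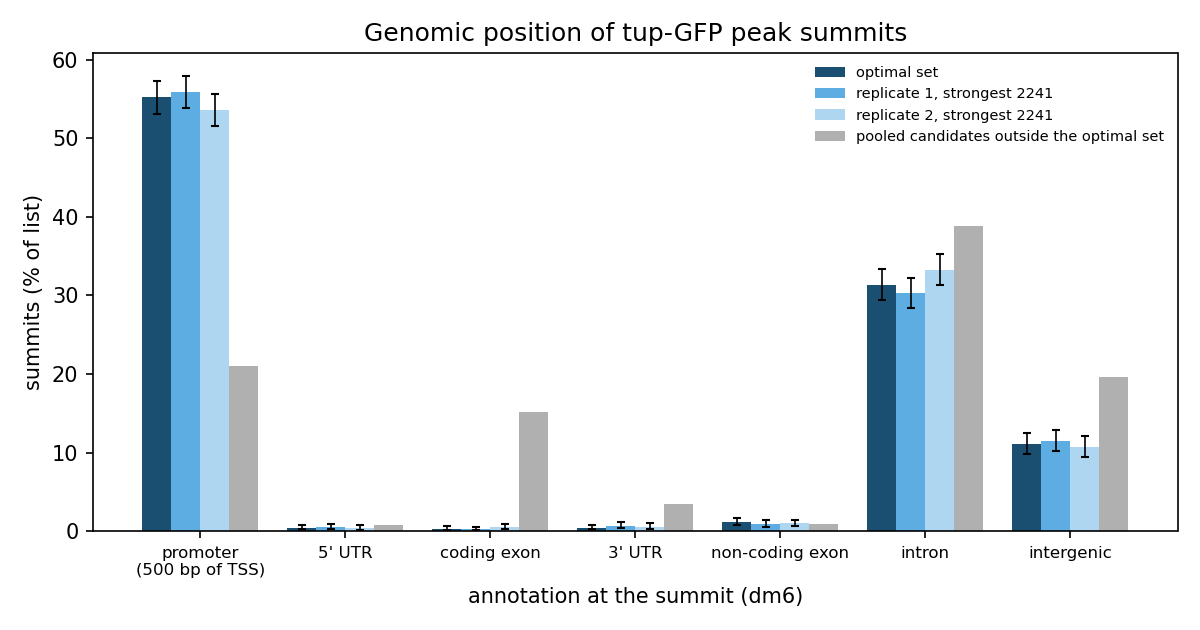
Share of summits in each annotation class (percent of each list) for the optimal set, the strongest 2241 peaks of each replicate and the pooled candidates outside the optimal set. Bars of the first 3 lists carry Wilson 95% intervals, and promoter shares lie between 53.6% and 55.9% in those lists against 21.03% in the candidates.

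Promoter peaks were also higher. Their median signal was 109 (interquartile range 84.8 to 160, 1237 peaks) against 95.5 (78.7 to 133, 1004 peaks) elsewhere, a difference of 13.5 (two-sided permutation test, p = 1e-05, the smallest it can give). The direction was the same in each replicate's own signal at these peaks. In replicate 1 the medians were 71.3 and 61.5, and in replicate 2 they were 42.9 and 38.6 (permutation test, p = 0.00038).

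The chromosome arms differed little apart from X and 4. The X chromosome held 374 optimal peaks (16.7%) against 13.4% of non-passing candidates (odds ratio 1.299, Fisher's exact test, adjusted p = 0.000138). Against its length, with 15.9 optimal peaks per Mb, X showed no excess (odds ratio 0.970, exact binomial test, adjusted p = 0.859). Chromosome 4 held 7 optimal peaks (0.312%) against 291 non-passing candidates (1.06%, odds ratio 0.292, Fisher's exact test, adjusted p = 0.000614). For the strongest peaks of replicate 2 alone that difference did not pass (odds ratio 0.636, Fisher's exact test, adjusted p = 0.866). Arms 2L (19.9% against 19.4%), 2R (18.5% against 18.2%), 3L (21.1% against 22.5%) and 3R (23.5% against 25.4%) did not pass the adjusted threshold, and Y held 0 optimal peaks. Arm 3R did pass for replicate 2 alone (odds ratio 0.876, Fisher's exact test, adjusted p = 0.0408) and above the median signal (0.829, adjusted p = 0.0414). Against arm length, 2L (odds ratio 1.205, exact binomial test, adjusted p = 0.00129) and Y (adjusted p = 6.82e-26) passed. Each replicate had only 1 candidate on Y, so optimal peaks were hardly possible there, and the Y test tells nothing about binding. Chromosome 4 also passed against its length (odds ratio 0.317, exact binomial test, adjusted p = 0.00126).

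Around tup itself there were 12 optimal peaks within 50 kb of the gene (2L 18859507 to 18881261, minus strand), where random windows of that length had a median of 1. This count lay above 99.7% of 10000 windows. The strongest was at the promoter of CG10602 (18857687 to 18857866, signal 283, rank 126), followed by an intergenic peak upstream of tup (18890204 to 18890299, signal 228, rank 221) and the promoter of CG10600 (18839500 to 18839883, signal 203, rank 287). The tup region held 2 of them, an intronic peak at 18878361 to 18878744 (signal 90.6) and an intergenic peak 3724 bp from the TSS at 18884793 to 18885176 (signal 113). Farther upstream lay 7, that of signal 228 included, whose nearest TSS were those of the non-coding genes lncRNA:CR44737, lncRNA:CR44739 and lncRNA:CR44738. Of the 12 peaks, 2 had no candidate summit of replicate 2 within 100 bp. Non-passing candidates were dense there as well, with 59 against a median of 26, above 99.3% of windows. Replicate 1 had 16 of its strongest peaks there and replicate 2 had 8.

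**Figure D2:**
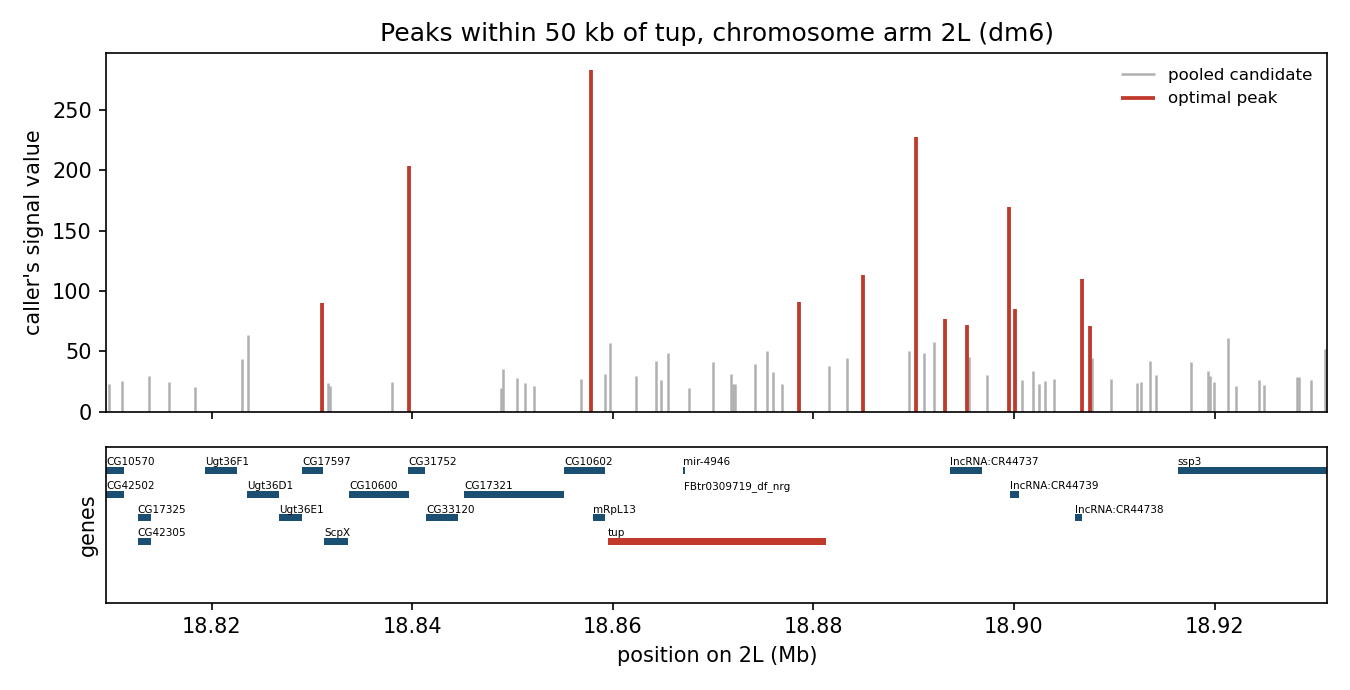
Caller's signal value (vertical axis, no unit) against position on 2L in Mb (dm6) for pooled candidates in grey and optimal peaks in red within 50 kb of tup, with annotated genes as bars underneath. The 12 optimal peaks span both sides of tup, and 8 of them lie upstream of its TSS.

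Bound genes were next counted in 22 gene lists. Optimal summits fell in the regions of 3772 of 18277 genes (20.6%), among them 3178 of 13968 protein-coding genes. The signal printed for a bound gene is that of the strongest peak in its region, which can lie nearest to another gene's TSS. Cytosolic ribosomal protein genes were bound more often than matched genes, and cuticle protein genes and odorant and gustatory receptor genes less often. The other 19 lists, including all 17 developmental and neuronal lists, did not pass the adjusted threshold with length matching. Without it, axon guidance genes (ratio 2.42, permutation test, adjusted p = 0.00352) and neuroblast and neurogenic genes (2.22, permutation test, adjusted p = 0.0362) passed as well. Of the 16 developmental and neuronal lists with a bound member, 9 then had a ratio more than 1.5 times higher, while 10 had one more than 1.5 times lower for summits within 1 kb of a TSS. By nearest TSS 7 moved up that far, among them segmentation (1.78), cardiac (1.45) and midgut genes (2.36), and 1 moved down. Above the median signal 2 moved up and 5 down.

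Of 88 cytosolic ribosomal protein genes, 41 (46.6%) were bound against 15.04 ± 3.5 (SD over random lists) expected, a ratio of 2.73 (permutation test, p = 2e-05, the smallest it can give, adjusted p = 0.00022). The strongest peaks lay at the promoters of RpL7 (2L 10200922 to 10201142, signal 378), RpL32 (3R 30046232 to 30046445, signal 297), RpS20 (signal 278) and RpS27 (signal 266). The RpL32 and RpS20 peaks were nearer to the TSS of CG7943 (111 bp against 198 bp) and of CG17271 (141 bp against 192 bp). RpL10 and RpL10Aa were unbound. The ratio was 4.41 with assignment by nearest TSS and 4.31 for summits within 1 kb of a TSS. None of the 94 cuticle protein genes was bound (0%, which allows up to 3.19%) against 15.9 expected (permutation test, p = 2e-05, the smallest it can give, adjusted p = 0.00022), with Cpr100A and Cpr11A as examples. Replicate 1 alone had 1 bound (1.06%) and replicate 2 alone had 2 (2.13%), both below expectation (permutation test, adjusted p = 0.00022 in each). Of 120 odorant and gustatory receptor genes, 10 (8.33%) were bound against 22.7 expected (permutation test, p = 0.00166, adjusted p = 0.0122). Gr5a (signal 230), Gr61a (172), Gr63a (126) and Gr93a (97.8) were bound, and Gr10a and Gr10b were not. The Gr61a and Gr63a peaks lay 94 bp and 5 bp from the TSS of CG13901 and Ccz1. The Gr5a peak was nearest to the TSS of Tre1, and only the Gr93a peak was nearest to its own. The receptor result did not pass when genes were matched on their number of non-passing candidates (ratio 0.552, permutation test, adjusted p = 0.160) or of all candidates, which include the optimal peaks (0.882, adjusted p = 1), assigned by nearest TSS (adjusted p = 0.0653), or tested with transposable elements counted as genes (adjusted p = 0.0695). Its ratio of 0.440 was 0.0734 for summits within 1 kb of a TSS and 0.232 above the median signal. Of 290 tRNA genes, 37 were bound against 44.9 expected (permutation test, adjusted p = 0.456). The tRNA:Tyr-GTA genes 1-6, 1-7 and 1-8 shared a peak of signal 381, and tRNA:Leu-TAA-2-1 and the neuronal gene Syx1A shared one of signal 263 (3R 24109177 to 24109359), while tRNA:Ala-AGC-1-1 and tRNA:Ala-AGC-2-1 were unbound. With assignment by nearest TSS the tRNA genes were above expectation (ratio 2.10, permutation test, adjusted p = 0.0380), and without length matching they were below it (ratio 0.618, permutation test, adjusted p = 0.00352). Their ratio of 0.824 was also above 1 with transposable elements counted as genes (1.41, permutation test, adjusted p = 0.136) and for summits within 1 kb of a TSS (1.31, permutation test, adjusted p = 0.524). Of 16 chorion and vitelline membrane genes, among them Cp15 and Cp16, 0 were bound (an upper limit of 18.8%) against 2.4 expected (permutation test, adjusted p = 0.385).

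**Figure D3:**
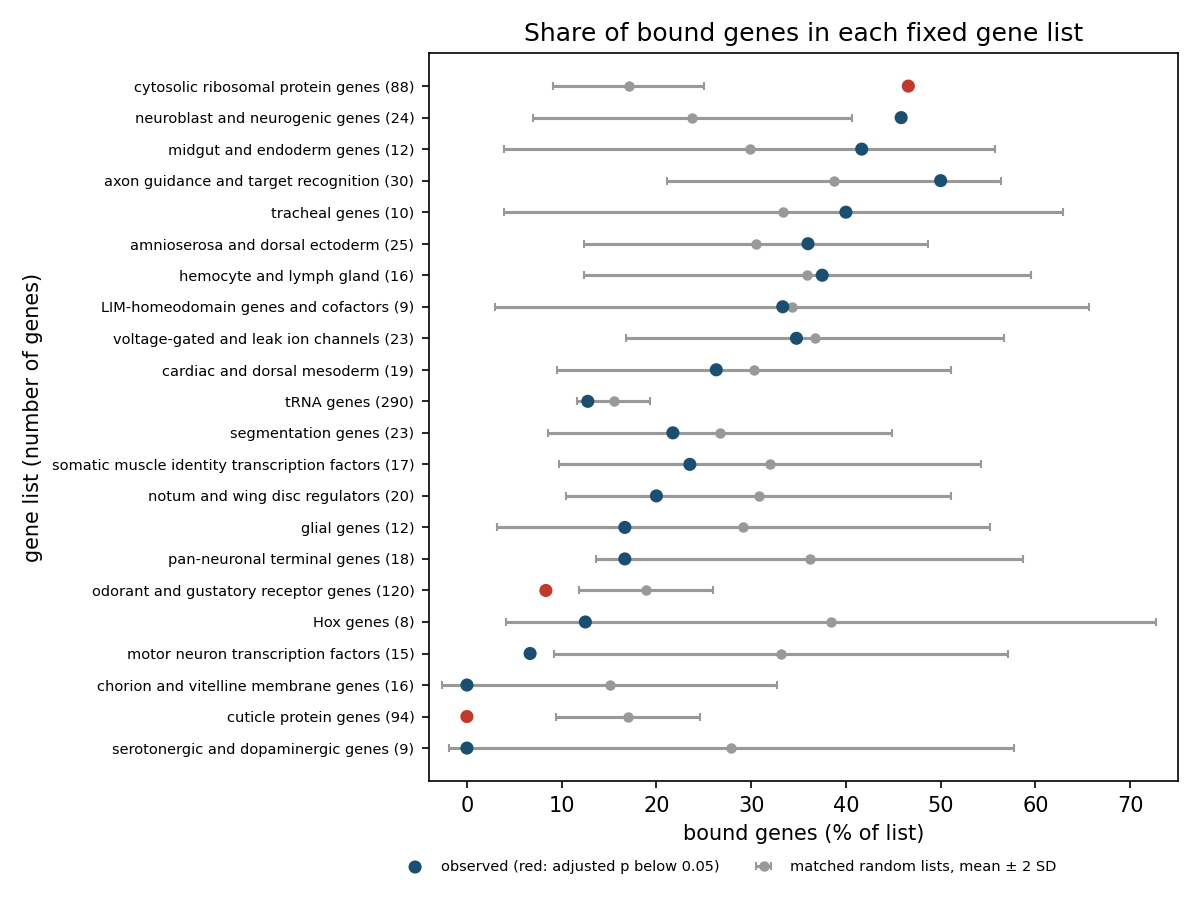
Percent of genes bound in each of 22 gene lists (horizontal axis, list size in parentheses), with grey points and bars for the mean and 2 SD of matched random lists. Ribosomal protein genes (46.6%) lie above their random lists, and cuticle protein (0%) and receptor genes (8.33%) below, in red.

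Among lists for tissues in which tup is known to act, cardiac and dorsal mesoderm genes had 5 of 19 members bound against 5.8 expected (permutation test, adjusted p = 1). The strongest peak of the muscle regulator Mef2 had rank 20 and lay 1051 bp from its nearest TSS, at the promoter of Pal1 (2R 9959760 to 9960073, signal 572), and org-1 (signal 170), the heart determinant tin (111) and Doc2 (99.98) were bound, while Doc1 and Doc3 were not. Of 25 amnioserosa and dorsal ectoderm genes, 9 were bound against 7.6 expected (permutation test, adjusted p = 0.942). They included ush, the JNK phosphatase gene puc (signal 145, 7653 bp from its nearest TSS) and the homeobox gene C15 (promoter, signal 103). Notum and wing disc regulators had 4 of 20 members bound against 6.2 expected (permutation test, adjusted p = 0.771), namely ush, hth (signal 115.2), caup (94.1) and vg (78.1). B-H1 and B-H2 were unbound. The vg peak lay at the promoter of Nmda1, 4113 bp from the nearest TSS of vg. Of 17 somatic muscle identity genes, 4 were bound against 5.4 expected (permutation test, adjusted p = 0.936), org-1, Poxm (signal 117), caup and vg. Dr and Kr were unbound.

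Neuronal lists lay on both sides of expectation, none past the adjusted threshold with length matching. Neuroblast and neurogenic genes had 11 of 24 members bound against 5.7 expected (permutation test, raw p = 0.0243, adjusted p = 0.134). The strongest were brat (intron, signal 180), the receptor gene N (intron, signal 154), E(spl)mbeta-HLH (141) and E(spl)mgamma-HLH (126), and E(spl)m5-HLH and amos were unbound. Genes of the E(spl) complex, which lie side by side and can share peaks, made up 6 of the 11. Of 15 motor neuron transcription factors only zfh1 was bound (intron, signal 70.7) against 5.0 expected (permutation test, raw p = 0.0381, adjusted p = 0.168). Dbx and HGTX were unbound. The N and zfh1 peaks had no candidate summit of replicate 2 within 100 bp. Replicate 1 alone had 0 of the 15 bound (permutation test, adjusted p = 0.0278) and replicate 2 alone had 2 (ratio 0.401, permutation test, adjusted p = 0.388). Axon guidance genes had 15 of 30 members bound against 11.6 expected (permutation test, adjusted p = 0.549), with the netrin receptor genes unc-5 (signal 215) and fra (124), beat-Ib (180) and caps (143) the strongest, and Con and Drl-2 unbound. Their ratio of 1.29 was 0.344 for summits within 1 kb of a TSS and 0.983 with matching on non-passing candidates. With matching on all candidates, which include the optimal peaks, it was 0.834. The beat-Ib peak lay at the promoter of lncRNA:CR44867, 51126 bp from the nearest TSS of beat-Ib. Of 23 ion channel genes, 8 were bound against 8.5 expected (permutation test, adjusted p = 1). KCNQ (215), Hk (163), NaCP60E (158) and sei (151) were the strongest, and Ca-alpha1D and Elk were unbound. The KCNQ, Hk and sei peaks were nearest to the TSS of mlt, CG12643 and tsr, and the NaCP60E peak to its own. Of 18 pan-neuronal genes, Syx1A (263), elav (253) and ChAT (114.8) were bound against 6.5 expected (permutation test, adjusted p = 0.385), and Gad1 and Rab3 were not. The Syx1A peak lay 135 bp from the TSS of CG18428 and 3438 bp from the nearest TSS of Syx1A. The ChAT peak lay at the promoter of lncRNA:CR46265, 14456 bp from the nearest TSS of ChAT. The pan-neuronal ratio of 0.461 was 0.792 for replicate 1 alone (5 bound) and 0.458 for replicate 2 alone (3 bound). No serotonergic or dopaminergic gene was bound (0 of 9, an upper limit of 33.3%, against 2.5 expected, permutation test, adjusted p = 0.377), with Ddc and DAT as examples.

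Lists of related and patterning genes did not differ from matched genes past the threshold. Of 9 LIM-homeodomain genes and cofactors, Bx (signal 94.8), Awh (94.4) and Lim1 (77.0) were bound against 3.1 expected (permutation test, adjusted p = 1), and Chi and CG4328 were unbound. The Awh peak had no candidate summit of replicate 2 within 100 bp. Of 8 Hox genes, only Antp was bound (signal 91.4) against 3.1 expected (permutation test, adjusted p = 0.543), and Abd-B and Dfd were unbound. The Hox ratio of 0.325 was 0.675 for replicate 1 alone and 0.641 for replicate 2 alone, with 2 bound in each. Segmentation genes had 5 of 23 members bound against 6.1 expected (permutation test, adjusted p = 1), led by slp2 (signal 279), ptc (115.1), bcd (103) and hry (96.1), with Kr and en unbound. The ratio of 0.813 was 0.657 for replicate 1 alone (4 bound) and 0.502 for replicate 2 alone (3 bound). The hry peak had a signal of 82.1 in replicate 1 and 8.32 in replicate 2, where the lowest candidate signal was 7.81. The bcd peak lay at the promoter of lncRNA:CR45593, 3466 bp from the nearest TSS of bcd.

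Lists for the other cell types of the embryo did not pass either. Hemocyte and lymph gland genes had 6 of 16 members bound against 5.7 expected (permutation test, adjusted p = 1), including N, hth and the peroxidasin gene Pxn (signal 105), with Hml and NimC1 unbound. Glial genes had 2 of 12 members bound, moody (promoter, signal 299) and pnt (121), against 3.5 expected (permutation test, adjusted p = 0.851), and Eaat1 and Nrx-IV were unbound. Of 10 tracheal genes, trh (112), pio (97.0), rib (84.0) and bnl (79.0) were bound against 3.3 expected (permutation test, adjusted p = 1), and btl and kni were not. Of 12 midgut and endoderm genes, 5 were bound against 3.6 expected (permutation test, adjusted p = 0.851), with fkh (promoter, signal 331), Fas3 (110), Hnf4 (76.5) and bin (69.6) the strongest and GATAe and grn unbound. These 3 lists moved between replicates. For replicate 1 and replicate 2 alone, glial genes had 3 and 4 bound (ratios 0.869 and 1.17, against 0.571), tracheal genes 2 and 3 (0.613 and 0.898, against 1.198), and midgut genes 3 and 6 (0.856 and 1.70, against 1.40).

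The sequence at the summits was AT-rich, and the Islet-type site was not more frequent than in candidates of like GC content. Mean GC content within 50 bp of the summit was 35.0% at optimal summits and 43.6% at non-passing candidates, and it was 33.7% for the strongest peaks of replicate 1 and 38.4% for those of replicate 2. The Islet-type site CTAATKG lay within 50 bp of 43 optimal summits (1.92%, Wilson 95% interval 1.43 to 2.57) against 75 of the matched candidates (3.35%, odds ratio 0.565, Fisher's exact test, adjusted p = 0.0134). The homeodomain core TAATTR was found at 18.6% against 22.4% (odds ratio 0.794, Fisher's exact test, adjusted p = 0.0116), but its direction turned against flanks of the same peaks (1.42, adjusted p = 2.3e-06) and without GC matching (1.32, adjusted p = 6.0e-06). The T-box site AGGTGT was at 3.39% against 2.14% (odds ratio 1.60, Fisher's exact test, adjusted p = 0.0375) and the DREF site TATCGATA at 1.43% against 0.312% (odds ratio 4.62, adjusted p = 0.000721). These calls depended on the candidates drawn. Over 100 other draws the Islet-type site passed in 13, with a median odds ratio of 0.676 (range 0.515 to 0.857), and the homeodomain core passed in 11. The T-box site passed in 0 draws and the DREF site in 56, with a median odds ratio of 2.69 (range 1.61 to 5.40). With candidates also matched on feature class none of these 4 motifs passed. The odds ratio was then 1.19 for DREF (Fisher's exact test, adjusted p = 0.600), 1.73 for T-box and 0.598 for the Islet-type site (adjusted p = 0.0556 for both). In each replicate alone the Islet-type (0.754 and 0.811), T-box (1.25 and 1.32) and DREF (1.86 and 2.13) odds ratios did not pass, and the homeodomain core passed for replicate 2 alone (0.759, Fisher's exact test, adjusted p = 0.00921). The GAGA factor, Zelda, GATA factor, E-box, NK2, MEF2 and Hox-Exd motifs did not pass.

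**Figure D4:**
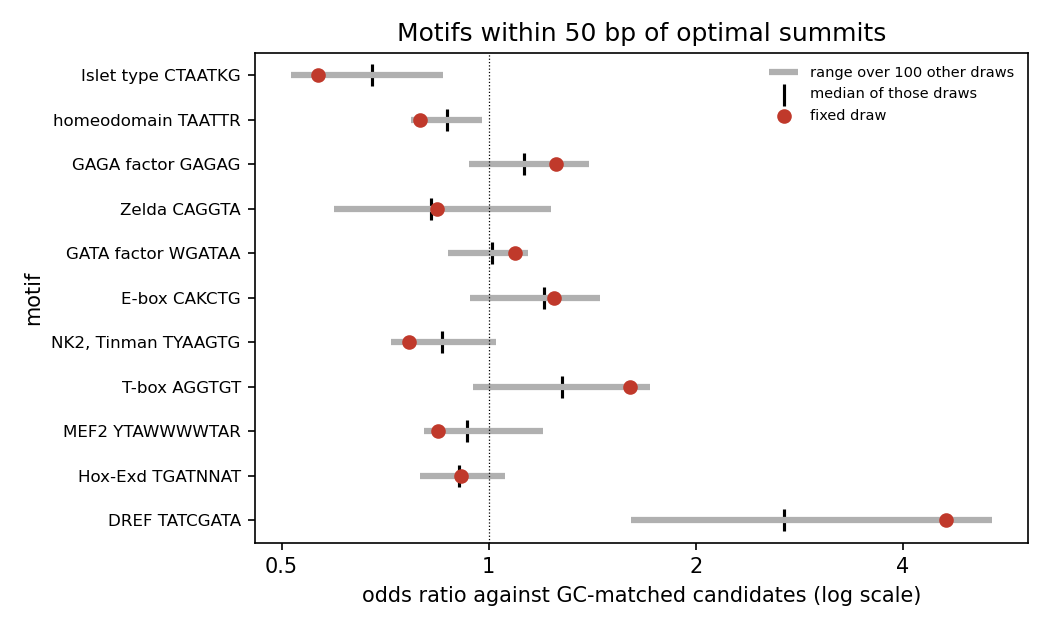
Odds ratio (log axis) of each of 11 motifs within 50 bp of optimal summits against GC-matched candidates, with red points for the draw fixed in advance, black marks for the median and grey bars for the range over 100 other draws. The Islet-type range (0.515 to 0.857) lies below 1 and the DREF range (1.61 to 5.40) above it. These ranges vary only the candidates drawn and are not confidence intervals. The Islet-type site passed in 13 of the draws and the DREF site in 56.

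Of the 2080 sequences of 6 bp, 27 passed the adjusted threshold, 14 higher and 13 lower at optimal summits. This scan was not repeated over the other draws of candidates, on which the calls of the 11 motifs depended. The leading pair was CGATAG, at 112 optimal summits (4.998%) against 38 candidates (1.70%, Fisher's exact test, adjusted p = 9.8e-07), and ACACTG, at 196 (8.75%) against 95 (4.24%, adjusted p = 9.8e-07). CTGTTA (5.80% against 2.95%), AACACT (8.43% against 4.95%) and CAACAC (7.36% against 4.28%) followed. TATATA was less frequent (10.6% against 15.04%, Fisher's exact test, adjusted p = 0.0032), but it was more frequent against flanks of the same peaks (odds ratio 2.04, adjusted p = 6.1e-12) and without GC matching (1.27, adjusted p = 0.0027). ATTATA and ATACAT turned in the same way. Only 1 of the 27 passed for optimal peaks above the median signal, and 5 did so when candidates were also matched on feature class. CGATAG (odds ratio 1.40 against 3.05, Fisher's exact test, adjusted p = 0.446), ACACTG (1.39 against 2.17, adjusted p = 0.307), CTGTTA and AACACT were not among those 5, which were CTCCTC, TATATA, CAACAC (1.78, Fisher's exact test, adjusted p = 0.005), ACAGTG (1.799, adjusted p = 0.0013) and ACATTA. ACAGTG also passed within 25 bp and 100 bp, without GC matching, against flanks and in each replicate alone, but not above the median signal (1.81, Fisher's exact test, adjusted p = 0.174). For replicate 1 alone 24 sequences passed, 7 of them among the 27, and for replicate 2 alone 16, 8 of them among the 27. CGATAG and ACACTG passed in both.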

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

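The background of protein-coding genes, the count of transposable elements as genes, the matching on non-passing candidates, the matching on feature class and the 100 other draws were chosen after the data were seen. Across all alternatives run, the promoter odds ratio stayed between 3.51 and 7.97, and the coding exon, 3' UTR, intron and intergenic shares and the promoter signal difference kept their direction and passed. The ribosomal and cuticle list calls also held throughout. Causes were not tested unless named. No paired analysis was possible because there is 1 group. Depth is unknown, so what it limits cannot be stated.

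Replicate sharing moved from 54.8% to 62.3% with any overlap and to 59.8% for the strongest 1120 peaks. The 5' UTR odds ratio (0.549) passed at a TSS distance of 1000 bp (0.313); each replicate alone gave 0.418 to 0.663. Against arm length, 2L (1.205) and Y (0, with only 1 candidate per replicate) passed, chromosome 4 still passed (0.317), and X turned to 0.970. Arm 3R passed above the median signal (0.829), and each replicate alone gave 0.876 to 0.922, passing for replicate 2. For chromosome 4 each replicate alone gave 0.241 to 0.636, the latter from replicate 2, where the call was lost. The count of lists past the threshold rose from 3 to 6 without length matching, by axon guidance (2.42), neuroblast and neurogenic (2.22) and tRNA genes (0.618). By nearest TSS, tRNA genes turned to a ratio of 2.10.

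The Islet-type site no longer passed within 25 bp (0.706), above the median signal (0.694) or against flanks of the same peaks (0.894). It also did not pass with feature class matching (0.598) or in each replicate alone (0.754 to 0.811). Over the other draws it passed in 13 of 100 (median 0.676). It still passed within 100 bp (0.648, Fisher's exact test, adjusted p = 0.00966) and without GC matching (0.660, adjusted p = 0.00998). The homeodomain core no longer passed within 25 bp (0.896) or 100 bp (0.884), above the median signal (0.807) or with feature class matching (0.949). Over the other draws it passed in 11 of 100 (median 0.871). Each replicate alone gave 0.759 to 0.863. The T-box site was lost within 25 bp (1.35) or 100 bp (1.16), above the median signal (1.06), without GC matching (1.07), against flanks (1.27), with feature class matching (1.73), over the other draws (1.28) and in each replicate alone (1.25 to 1.32). The DREF site was lost within 25 bp (1.29), above the median signal (2.82), against flanks (1.23), with feature class matching (1.19) and in each replicate alone (1.86 to 2.13). Within 100 bp it passed with a lower odds ratio (2.15, Fisher's exact test, adjusted p = 0.0011). Without GC matching (background 43.6% GC against 35.0%) the DREF odds ratio was 3.09, and homeodomain turned to 1.32, MEF2 to 1.89, Hox-Exd to 1.301, GAGA factor to 0.848 and E-box to 0.736, while Zelda (0.710) and GATA factor (1.43) passed. Against flanks (43.1% GC), homeodomain turned to 1.42, MEF2 to 1.86, Hox-Exd to 1.37, GAGA factor to 0.559 and E-box to 0.794, while GATA factor (1.19) passed. Within 100 bp the GAGA factor motif passed (1.43). The count of 6 bp sequences moved from 27 to 2 within 25 bp, 116 within 100 bp, 1269 without GC matching, 1 above the median signal, 1091 against flanks and 7 with feature class matching, and each replicate alone gave 16 to 24.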

Other observations

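The gene groups, the count of opposite-strand promoters and the tests in this part were chosen after the main results were seen. Further groups of broadly expressed and tissue-restricted genes were counted by the same length-matched test, adjusted over 12 groups. Mitochondrial ribosomal protein genes were bound more often than matched genes, with 22 of 73 bound against 10.6 expected (ratio 2.08, permutation test, adjusted p = 0.0036). Their strongest peaks were those in the regions of mRpS23 (signal 672), mRpL41 (509.97), mRpS10 (468) and mRpL23 (415). Cytochrome P450 genes, many of them detoxification enzymes, had 4 of 87 members bound against 18.9 expected (adjusted p = 0.00024), odorant binding protein genes 1 of 51 against 7.1 (permutation test, adjusted p = 0.0266) and Osiris genes 0 of 23 against 4.8 (permutation test, adjusted p = 0.0266). When genes were matched on their number of non-passing candidates, cytochrome P450 genes (ratio 0.250 against 0.212, permutation test, adjusted p = 0.00264) and odorant binding protein genes (0.127 against 0.140, permutation test, adjusted p = 0.0205) still passed. Mitochondrial ribosomal protein genes (ratio 1.47, permutation test, adjusted p = 0.181) and Osiris genes (0 against 4.4 expected, adjusted p = 0.0586) did not. With all candidates counted, the optimal peaks included, none of the 4 passed, with ratios of 0.335, 0.210, 1.38 and 0 in that order. The test treats genes as independent, so p-values can be too small for groups whose members lie side by side.

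The other 8 groups did not pass. Polycomb and trithorax group genes had 7 of 15 members bound against 4.8 expected (permutation test, adjusted p = 0.553), among them ph-p (signal 794), osa (400.1), Psc (328) and brm (316). Insulator protein genes had 4 of 10 bound, Chro, Cp190 (signal 233), mod(mdg4) and BEAF-32, against 2.4 expected (permutation test, adjusted p = 0.553). Proteasome subunit genes had 6 of 48 bound against 8.5 expected (permutation test, adjusted p = 0.553) and NADH dehydrogenase subunit genes 10 of 40 against 6.9 (adjusted p = 0.539). Translation initiation factor genes had 11 of 44 bound against 9.97 expected (adjusted p = 0.822) and heat shock protein genes 6 of 19 against 4.1 (permutation test, adjusted p = 0.553). Jonah protease genes had 1 of 16 bound (permutation test, adjusted p = 0.667) and spliceosomal snRNA genes 2 of 32 (permutation test, adjusted p = 0.539).

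Many promoter peaks had start sites of genes on both strands nearby. Of 1237 optimal promoter summits, 517 (41.8%, Wilson 95% interval 39.1 to 44.6) had start sites of different genes on both strands within 500 bp, against 17.1% of 5760 non-passing promoter candidates (odds ratio 3.49, Fisher's exact test, p = 5.4e-73). The share was 42.3% for the strongest peaks of replicate 1 and 37.7% for those of replicate 2. Summits were not matched on distance to the TSS or on local gene density, so effects of either cannot be told apart.

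The excess at cytosolic ribosomal protein genes was weighed against 3 explanations. A general density of candidate peaks at these genes does not account for it as a whole, since the ratio of bound to expected genes was still 2.01 (permutation test, adjusted p = 0.00022) after matching on that number, which includes the optimal peaks, and 2.35 on that of non-passing candidates, against 2.73 before. For recruitment at Islet-type sites, 2 of the 47 optimal peaks in these regions (4.26%, Wilson 95% interval 1.17 to 14.2) held CTAATKG within 50 bp. Most of these peaks thus lacked the exact site. Among all optimal peaks the share was 1.92% (43 of 2241), so a low share cannot tell recruitment from its absence. More divergent sites were not searched, and this explanation stays open. Promoters of broadly expressed genes in general remain a candidate explanation, as mitochondrial ribosomal protein genes showed a ratio of 2.08 with length matching, but it was 1.47 with matching on non-passing candidates, against 2.35 for the cytosolic genes, and proteasome subunit genes had 0.707 and 0.650. Signal that tagged chromatin proteins or the antibody give at active promoters was not tested, because no mock or other-factor sample was analysed here.

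The cluster of 12 optimal peaks around tup may come from extra copies of the locus on the transgene or from binding of tup there. Windows with a like number of optimal peaks were taken from a separate, larger random draw that left out the tup window. The 59 non-passing candidates around tup lay at percentile 93.1 of these 1446 windows, between the bounds set for either outcome. The windows overlap each other and cover far fewer separate loci, so this percentile is rough. Extra copies cannot be told apart from a locus rich in regulatory DNA. Islet-type sites were found at 2 of the 12 peaks, at 2L 18884793 to 18885176 and 18907367 to 18907750, against 41 of 2229 other optimal peaks (1.84%, Fisher's exact test, p = 0.021). This is consistent with direct binding at those peaks but rests on 2 peaks, and both explanations stay open.

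Replicate 1 had 460 candidates on chromosome 4 and replicate 2 had 103, although both lists held 30000 peaks. Mean GC content of the candidates was 41.1% in replicate 1 and 45.7% in replicate 2, and on chromosome 4 it was 34.5% and 41.9%. GC deciles off chromosome 4 predicted 112 candidates for replicate 1 from those of replicate 2 (2.5% of the excess) and 347 for replicate 2 from those of replicate 1 (31.6%), which argues against GC content as the whole cause and leaves open that it may account for part. The strongest 2241 peaks held 9 on chromosome 4 in replicate 1 and 5 in replicate 2. Depth stays open because it is unknown, and no biological explanation was tested, since the design names no difference between the replicates.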
